A study of Homo sapiens with 6 samples.

How the data were processed

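Chromatin immunoprecipitation on tiling microarrays (ChIP-chip) was available for 3 proteins in the human erythroleukemia line K562: GATA-1, NLI and RNA polymerase II. Each protein had 2 arrays, numbered as replicates 1 and 2 in the labels, so 6 arrays in all. Per the labels, immunoprecipitated DNA carried Cy5 and the input DNA of the same replicate carried Cy3 on every array. The dyes were not swapped, so a dye bias is part of every ratio. Nothing in the labels says that the 2 arrays of a protein came from separate cultures, and p-values therefore measure only the spread between these arrays, which may be technical. The labels give the name of each array's protein and cell line; in the description of RNA polymerase II replicate 2 the cell line's name has 2 digits transposed, and the array was taken as K562 from its other labels.

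Each array had a deposited scanner table for each of its 2 channels, which held the intensity of every probe on a linear scale at 635 nm (immunoprecipitated DNA) or 532 nm (input). Per the file headers, these intensity values were extracted with NimbleScan, version 2.3.78 for the replicate 1 arrays and 2.4.27 for the replicate 2 arrays, on the 24th array of a human tiling set built on genome build hg18. No background had been subtracted. The headers also place the replicate 1 arrays on 1 extraction day and the replicate 2 arrays on another, so the replicate number is also a batch that holds 1 array of each protein. Within a day no protein has a spread, so counts of enriched windows were not made per day, and the day entered as a block instead. The deposited value table held log2 ratios, rounded to 2 decimals. Set against the scanner tables, every value equalled the log2 of the 635 nm over the 532 nm intensity less a single constant per array (0.18 to 0.83), within a tolerance of 0.01 for 100% of probes. This settled its scale and direction, and its column medians were 0 to 0.01. How the constant was chosen is not given in the sources used here.

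The array held 383527 experimental probes and 5780 random control probes. The experimental probes tiled chromosome 10 from 99783524 to 135370801 (199992 probes) and chromosome 11 from 50001 to 35341352 (183139 probes), with 396 more on an unplaced part of chromosome 10. Median spacing was 100 bp, and repeats were left as gaps. Positions are those of the files, on hg18. The gene table supplied with the data is on another assembly, GRCh38. It was used only for which genes neighbour the β-like globin genes, and no gene was placed on the array from it. Regions are therefore given by coordinates, and the tests planned per promoter, per gene list and per globin locus were not run.

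Signal over background was modest. Median probe intensity was 589.89 to 938.33 in the immunoprecipitated channel and 915.22 to 1379 in the input channel. These medians were 1.89 to 2.41 times and 1.38 to 2.02 times the median of the random control probes, and the lowest input value belonged to NLI replicate 1. Between 50 and 169 probes per array were saturated in the immunoprecipitated channel and 44 to 289 in the input channel, and they were kept. The number of arrays limits the precision.

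The log2 ratio of immunoprecipitated over input intensity was taken per probe and centred on the median of each array, with no loess or quantile step. Experimental probes were averaged in fixed 500 bp windows with at least 3 probes, which gave 78183 windows. A linear model with a mean per protein was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 residual and 10.3 prior degrees of freedom). All tests were two-sided with Benjamini-Hochberg adjustment over all windows and a threshold of 0.05. A window counted as enriched when its mean lay above 0 and as depleted when it lay below 0. The 3 differences between proteins came from the same fit. A difference in ratio between antibodies is not a difference in the number of bound molecules, because antibodies differ in efficiency. Adjacent enriched windows were merged into regions, and a window with too few probes ended a region. Overlaps of enriched windows were set against the product of independent lists and against 1000 circular shifts of the calls of the first protein along the tiled windows (a one-sided permutation test, smallest possible p 0.001).

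Choices were made before the data were examined unless stated otherwise. The rule for the regions named took, for each protein, the 10 merged regions with the highest window among those above 0 on both arrays. For each difference it took the 10 windows with the largest difference in each direction whose arrays did not overlap between the 2 proteins. The windows named between 5.15 and 5.35 Mb of chromosome 11 and those named for the difference between GATA-1 and NLI were chosen after their values were seen.

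Alternatives were windows of 250 bp and 1000 bp, normexp background correction of each channel with an offset of 50, loess of the ratio on mean intensity within arrays, quantile normalization between arrays, Tukey biweight centring, the deposited log2 ratios, removal of the 10% of probes dimmest in the input, a minimum log2 ratio of 1, the replicate number as a block, fits of only the 4 arrays compared, and each array left out in turn. Added after seeing the data were a test of GATA-1 against NLI restricted to windows enriched over the mean of their 4 arrays, normexp fitted on the random control probes, and the array correlations after loess and after normexp. The fit was tested on 78183 simulated windows, 400 of which had known log2 ratios added for GATA-1 or RNA polymerase II. It recovered 90% of the 100 GATA-1 windows set at a log2 ratio of 1 and 84% of the 100 RNA polymerase II windows. Of differences of 1 between GATA-1 and NLI it recovered 25%, and of differences of 2 it recovered 100%.

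Because replicate numbers mark the extraction days, the deviations of same-numbered arrays from their protein's mean were correlated across windows. The correlations were -0.02 for GATA-1 with NLI, 0.0014 for GATA-1 with RNA polymerase II and -0.06 for NLI with RNA polymerase II.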

Results

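Binding of 3 proteins to chromatin was compared in K562 cells, a human erythroleukemia line, by chromatin immunoprecipitation on tiling arrays. GATA-1 is a zinc-finger transcription factor needed for red cell development. NLI, also known as Ldb1, is an adaptor that does not bind DNA itself and is recruited by DNA-binding factors, GATA-1 complexes among them. RNA polymerase II transcribes protein-coding genes. The study's title concerns repression and re-activation of the γ-globin genes by complexes that contain NLI. Each protein had 2 arrays, each hybridised with its own input DNA, and the values below are mean log2 ratios of immunoprecipitated over input DNA in 500 bp windows (SD over 2 arrays). Each array was centred on its median, which was -0.82 to -0.17 before centring. A value of 0 is therefore the typical ratio of an array and not equality with input. Enriched over input and below input mean above and below that median here, and folds are relative to it. The arrays tiled 99.8 to 135 Mb of chromosome 10 and 0.050 to 35.3 Mb of chromosome 11 on hg18, and 78183 windows were tested. The median input intensity was 1.38 to 2.02 times that of the random control probes.

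GATA-1 was enriched over input in 916 windows (1.17% of those tested), which formed 738 separate regions. Of these regions 82.2% were a single window, and the longest reached 3.0 kb, on chromosome 11 from 34595001 to 34598000. The highest window lay on chromosome 11 at 33923001 to 33923500, with a log2 ratio of 3.20 ± 0.05 (SD, n = 2), a 9.20-fold enrichment. It was followed by windows on chromosome 11 at 8966501 to 8967000 (3.14 ± 0.48) and 3812501 to 3813000 (3.04 ± 0.28) and on chromosome 10 at 100212501 to 100213000 (3.04 ± 0.51) and 112607001 to 112607500 (2.93 ± 0.25). The other 5 of the 10 highest regions began at 100210501 and 127494501 on chromosome 10 and at 34580501, 210501 and 27350001 on chromosome 11, with log2 ratios of 2.74 to 2.84. Enriched windows made up 1.45% of chromosome 11 and 0.91% of chromosome 10, a difference that was not tested. The megabase from 12 to 13 Mb of chromosome 11 held the most, 60, and 5 of the 70 megabases with at least 500 windows tested held 0. GATA-1 fell below input in 60 windows, against 9 without GATA-1 replicate 2, 19 with either RNA polymerase II array left out and 131 with 1000 bp windows. The ratio rose with probe intensity on every array (r = 0.36 to 0.72 across probes over the 6 arrays), and after loess removal of that trend 274 windows remained enriched, all of them among the 916 and including the 10 highest. Without GATA-1 replicate 2 the enriched count was 309, and with normexp background correction fitted on the random control probes it was 0 (limma, 3099 windows at an unadjusted p under 0.05).

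NLI was enriched in 1131 windows (1.45%) in 920 regions, 82.3% of them a single window. Its highest window was that of GATA-1, at 33923001 to 33923500 of chromosome 11, with a log2 ratio of 3.52 ± 0.10 (SD, n = 2), an 11.4-fold enrichment. Next came chromosome 11 at 8966501 to 8967000 (3.47 ± 0.49) and 34581501 to 34582000 (3.22 ± 0.14), and chromosome 10 at 100212501 to 100213000 (3.18 ± 0.23) and 126396501 to 126397000 (3.03 ± 0.47). Windows at 18671501 to 18672000 of chromosome 11 (2.98 ± 0.30), 130287501 to 130288000 of chromosome 10 (2.92 ± 0.37) and 12179001 to 12179500 of chromosome 11 (2.90 ± 0.34) were also among its 10 highest. The megabases richest in NLI windows were 12 to 13 Mb (59 windows) and 3 to 4 Mb (53 windows) of chromosome 11. NLI fell below input in 441 windows, so that 71.9% of its calls were enrichments, but this split was not stable. With 1000 bp windows it was 1624 enriched against 1693 depleted windows (49.0% enrichments), after quantile normalization 1067 against 111 (90.6%), and with the replicate block 925 against 154. Depleted windows numbered 34 without the dimmest probes, 12 without NLI replicate 1, 36 without NLI replicate 2, 87 with either RNA polymerase II array left out and 743 with either GATA-1 array left out. After loess the calls were 126 enriched and 0 depleted windows (100% enrichments; limma, 1969 windows below 0 at an unadjusted p under 0.05), and the enriched count was 469 without NLI replicate 1 and 207 without replicate 2. With normexp fitted on the random control probes 0 windows were enriched (limma, 7258 windows at an unadjusted p under 0.05).

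RNA polymerase II covered far more of the tiled sequence, with 8090 enriched windows (10.3%) in 3453 regions. Of these regions 93 reached 5000 bp or more, and the longest spanned 18 kb on chromosome 11 from 1531501 to 1549500, whereas the longest region was 3.0 kb for GATA-1 and 2.5 kb for NLI. The highest window lay on chromosome 11 at 5227501 to 5228000, with a log2 ratio of 3.73 ± 0.15 (SD, n = 2), a 13.3-fold enrichment. Windows at 8660501 to 8661000 (3.71 ± 0.24), 5232501 to 5233000 (3.59 ± 0.20), 18612501 to 18613000 (3.56 ± 0.45), 10787001 to 10787500 (3.54 ± 0.19) and 5247501 to 5248000 (3.53 ± 0.43) of the same chromosome followed, so that 3 of the 6 highest lay between 5227501 and 5248000. On chromosome 10 the highest were 102123001 to 102123500 (3.40 ± 0.09) and 103995001 to 103995500 (3.35 ± 0.39). Enrichment was uneven along the chromosomes. The median megabase had 5.73% of its windows enriched, the first megabase of chromosome 11 had 81.4% (917 of 1127 windows; 605, or 53.7%, after loess), and each megabase from 21 to 27 Mb of chromosome 11 had at most 1.57%. RNA polymerase II fell below input in 880 windows, in 36 without its replicate 1 and in 252 without its replicate 2. The enriched count was 4927 after loess, 1450 with normexp fitted on the random control probes, 3622 without RNA polymerase II replicate 1 and 5337 without replicate 2.

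**Figure D1:**
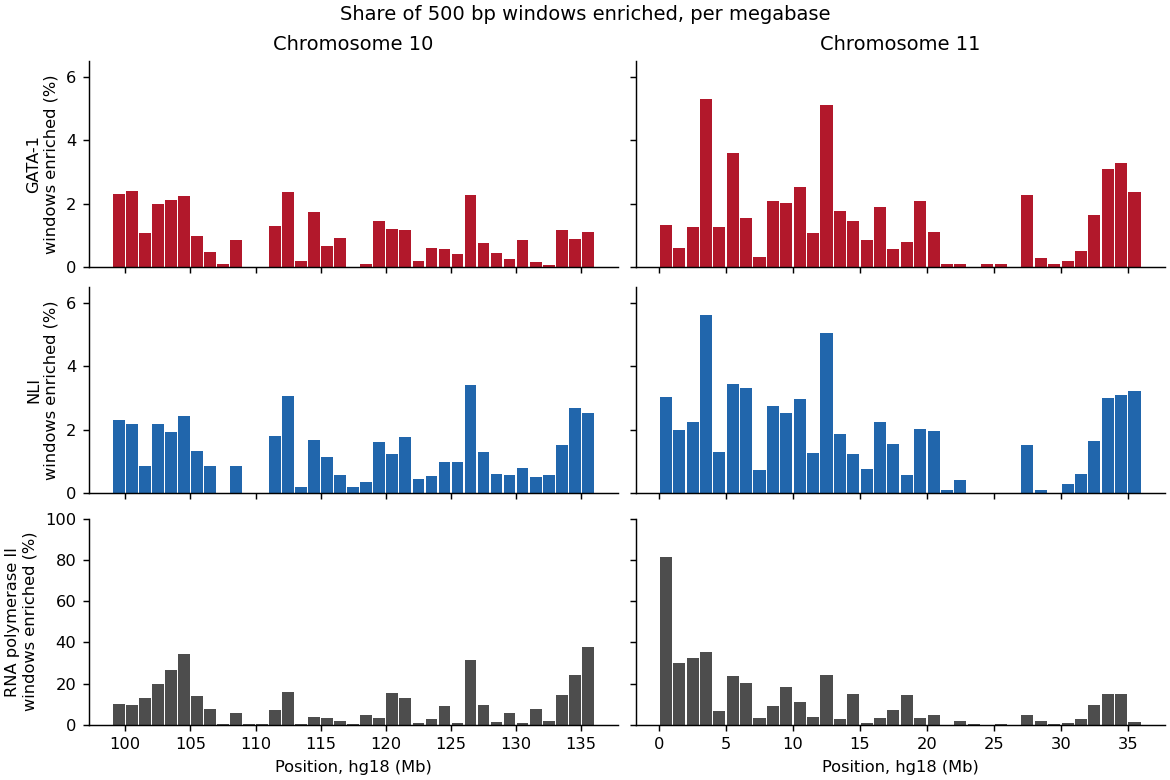
Share of 500 bp windows enriched over input (percent, vertical axes) in each megabase (horizontal axes, Mb on hg18) of the tiled parts of chromosomes 10 and 11, for GATA-1, NLI and RNA polymerase II (bars, from the fit over 6 arrays; the vertical scale differs between proteins). RNA polymerase II reached 81.4% in the first megabase of chromosome 11 (53.7% after loess, not drawn), and GATA-1 and NLI both had over 5% only at 3 to 4 Mb and 12 to 13 Mb of that chromosome.

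GATA-1 and NLI shared most of their strongest sites. Of the 10 highest regions of each, 6 had the same highest window in both lists, and all 10 GATA-1 windows were enriched for NLI and all 10 NLI windows for GATA-1. Over all windows, 458 were enriched for both, which is 50% of the GATA-1 windows and 40.5% of the NLI windows. Independent lists would share 13.3 windows, and 1000 circular shifts of the calls gave at most 27 (permutation test, one-sided, p = 0.001, the smallest these shifts can give). Over the 916 GATA-1 windows the median NLI log2 ratio was 0.66 and 96.2% lay above 0, and over the 1131 NLI windows the median GATA-1 ratio was 0.54 and 92.8% lay above 0. After loess 89 windows were shared against 0.44 expected. The shared count was 194 without GATA-1 replicate 2 and 148 without NLI replicate 2. Within the first extraction day, the GATA-1 and NLI arrays had 284 of their top 1000 windows in common, and within the second 444, against 12.8 expected by chance.

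The direct test of GATA-1 against NLI found 0 windows that differed (limma, smallest adjusted p = 0.186; 4382 windows had an unadjusted p under 0.05, against 3909 expected by chance, and the fit after loess also called 0). The test had limited reach. In simulated data, which also held 100 windows with a difference of 2, it recovered 25% of differences of 1 on the log2 scale. In the data even a difference of 1.74, at 12137001 of chromosome 11, was not called (limma, adjusted p = 0.186). The 25% may therefore overstate the reach in these data. After these 0 calls were seen, the test was restricted to the 4429 windows enriched over the mean of the 4 arrays. It called 14 windows there, 11 with the higher ratio for GATA-1 and 3 with the higher ratio for NLI. The largest was at 12137001 to 12137500 of chromosome 11, where GATA-1 stood at 2.62 ± 0.20 and NLI at 0.89 ± 0.14 (adjusted p = 0.012). At 5340001 to 5340500 of chromosome 11 GATA-1 stood at 1.88 ± 0.22 and NLI at 0.51 ± 0.21 (adjusted p = 0.014). The 3 windows with more NLI were 125302001 to 125302500 of chromosome 10 (GATA-1 0.64 ± 0.07, NLI 1.71 ± 0.19), 126396001 to 126396500 of chromosome 10 (0.67 ± 0.21 and 1.66 ± 0.01) and 12985501 to 12986000 of chromosome 11 (0.05 ± 0.14 and 1.10 ± 0.02). Over all windows, the fit without GATA-1 replicate 1 called 5 and the fit without GATA-1 replicate 2 called 8.

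**Figure D2:**
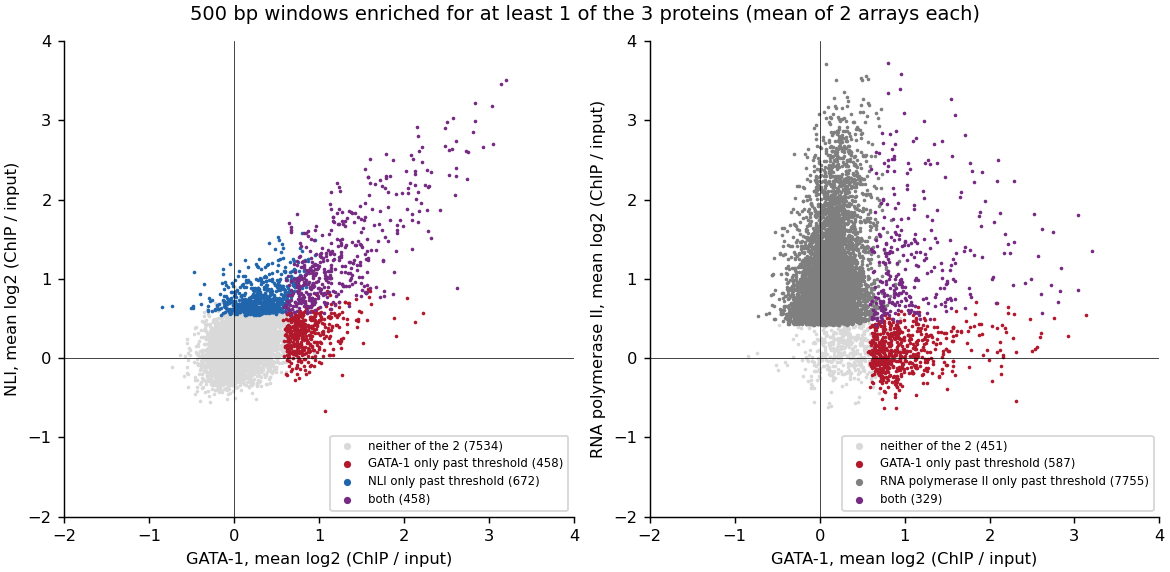
Mean log2 ratio of immunoprecipitated over input DNA (2 arrays per protein) for the 9122 windows of 500 bp enriched for at least 1 of the 3 proteins, GATA-1 on the horizontal axes against NLI (left) and RNA polymerase II (right). Each point is a window and colours give the proteins it was enriched for; 458 windows were enriched for both GATA-1 and NLI, and 329 for both GATA-1 and RNA polymerase II.

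RNA polymerase II and GATA-1 differed in 4343 windows, 563 with the higher ratio for GATA-1 and 3780 with the higher ratio for RNA polymerase II. The largest excess of GATA-1 lay at 126132501 to 126133000 of chromosome 10, where the difference was 2.85 (SE 0.28; GATA-1 2.32 ± 0.64, RNA polymerase II -0.53 ± 0.31; adjusted p = 3.7e-05). It was followed by 112607001 to 112607500 of chromosome 10 (difference 2.65, SE 0.25), and the 10 largest differences in this direction were 2.29 or more. The largest excess of RNA polymerase II lay at 8660501 to 8661000 of chromosome 11, where GATA-1 stood at 0.07 ± 0.07 and RNA polymerase II at 3.71 ± 0.24. Between NLI and RNA polymerase II 3841 windows differed, 500 with more NLI and 3341 with more RNA polymerase II. NLI exceeded RNA polymerase II most at 8966501 to 8967000 of chromosome 11 (difference 2.92, SE 0.28), 18671501 to 18672000 of chromosome 11 (2.89, SE 0.22) and 126132501 to 126133000 of chromosome 10 (2.88, SE 0.28). Without RNA polymerase II replicate 1, windows with more GATA-1 numbered 159 and windows with more RNA polymerase II 1774, and in the comparison with NLI the counts were 134 and 1406. Without RNA polymerase II replicate 2, 370 windows had more GATA-1 and 327 more NLI. The excess of GATA-1 was called in 332 windows without GATA-1 replicate 2, and that of NLI in 215 without NLI replicate 2, where 1890 had more RNA polymerase II, and in 302 after loess. After quantile normalization 604 windows had more GATA-1 and 2014 more RNA polymerase II, and 411 had more NLI and 1487 more RNA polymerase II.

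Many GATA-1 and NLI windows also carried RNA polymerase II. It was enriched in 329 of the 916 GATA-1 windows (35.9%; 94.8 expected, at most 172 in the circular shifts) and in 439 of the 1131 NLI windows (38.8%; 117 expected, at most 195), and 211 windows were enriched for all 3 proteins. In windows of matched intensity, 245 of the 329 and 346 of the 439 shared windows were expected. Of the 10 highest GATA-1 regions, 7 were enriched for RNA polymerase II, with ratios from 0.71 ± 0.29 at 210501 to 211000 to 1.81 ± 0.50 at 3812501 to 3813000 of chromosome 11. After loess 4 of these 7 calls held. At 112607001 to 112607500 of chromosome 10, which did not pass, the ratio was 0.28 ± 0.17. Over the 8090 RNA polymerase II windows the median ratio was 0.13 for GATA-1 and 0.21 for NLI. Of the highest windows of its 10 highest regions, 4 were called for GATA-1 and 1 for NLI. None of these 5 calls passed after loess, where the 4 GATA-1 ratios went from 0.80, 0.95, 0.95 and 0.80 to 0.61, 0.76, 0.75 and 0.64 and the NLI ratio from 0.87 to 0.56. After loess 69 windows were shared with GATA-1 and 34 with NLI (17.3 and 7.94 expected). Leaving out GATA-1 replicate 2 gave 119 windows shared with GATA-1, leaving out RNA polymerase II replicate 1 gave 178, and leaving out NLI replicate 2 gave 98 shared with NLI.

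Between 5150001 and 5350000 of chromosome 11, a stretch chosen because 3 of the 6 highest RNA polymerase II windows lay there, RNA polymerase II was enriched in 113 of 266 windows (42.5%, against 11.6% over the chromosome). GATA-1 was enriched in 21 windows, NLI in 16 and both in 10. After loess the whole stretch held 5 GATA-1, 2 NLI and 96 RNA polymerase II windows. The β-globin cluster, with the γ-globin genes named in the study's title, is known to lie on the short arm of this chromosome, but no hg18 annotation was used and the windows were not assigned to genes. The highest window for both factors was 5262501 to 5263000, with GATA-1 at 2.17 ± 0.63, NLI at 2.80 ± 0.41 and RNA polymerase II at 1.33 ± 0.12. Its RNA polymerase II call did not pass after loess (log2 ratio 0.96, limma, adjusted p = 0.0546). To either side lay 5253501 to 5254000 (GATA-1 1.77 ± 0.76, NLI 2.15 ± 0.69, RNA polymerase II 2.46 ± 0.13) and 5266001 to 5266500 (1.39 ± 0.63, 1.47 ± 0.37 and 2.46 ± 0.22). At 5258501 to 5259000 NLI stood at 1.59 ± 0.17 and GATA-1 at 0.67 ± 0.30. At 5245001 to 5245500 GATA-1 reached 1.60 ± 0.51, NLI 0.88 ± 0.23 and RNA polymerase II 3.08 ± 0.42. Of 10 windows with a GATA-1 or NLI ratio of at least 1 here, 9 were called for both factors, but most of these pairs of calls were fragile. The GATA-1 call at 5258501 (adjusted p = 0.0476) was lost in 11 alternatives, the replicate block among them (adjusted p = 0.0647, leaving 8 windows called for both). The NLI calls at 5222501 and 5245001 were lost in 5 alternatives each and that at 5202501 in 4. Normexp fitted on the random control probes ended every GATA-1 and NLI call, and in the other alternatives run for these windows only 5262501 kept both calls throughout. After loess 5 of the 10 passed for GATA-1 and 2 for NLI, with 5262501 to 5263000 passing for both. The calls at 5253501 and 5266001 did not pass after loess, where GATA-1 stood at 1.58 and 1.24 (adjusted p = 0.0639 and 0.0649) and NLI at 1.84 and 1.21 (adjusted p = 0.0546 and 0.117). They also did not pass for GATA-1 without its replicate 2 and for NLI without its replicate 2.

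**Figure D3:**
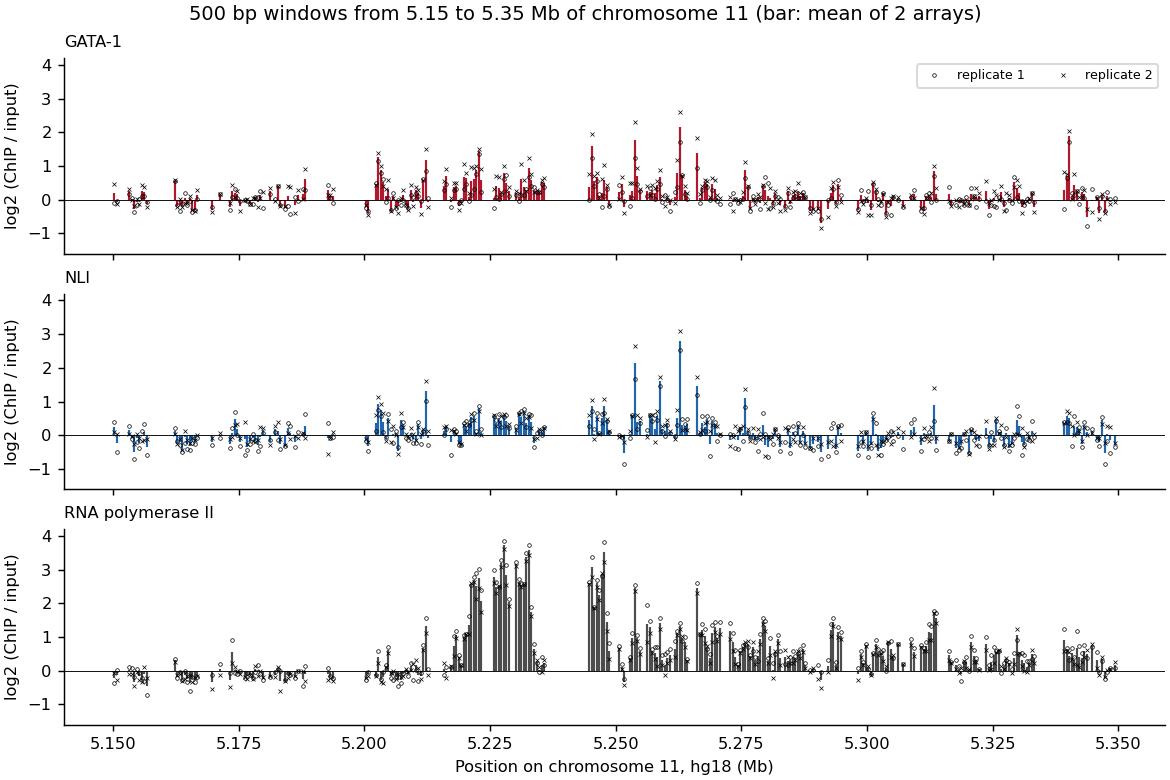
Log2 ratio of immunoprecipitated over input DNA (vertical axes) in 500 bp windows between 5.15 and 5.35 Mb of chromosome 11 (horizontal axis, hg18) for GATA-1, NLI and RNA polymerase II; bars are means of 2 arrays, circles replicate 1 and crosses replicate 2, and gaps are windows with fewer than 3 probes. RNA polymerase II peaked at 3.73 in the window that starts at 5227501, and GATA-1 (2.17) and NLI (2.80) peaked together at 5262501.

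Across all windows, which are not independent replicates, the Pearson correlation between replicate arrays was 0.79 for RNA polymerase II, 0.41 for GATA-1 and 0.47 for NLI. The 4 pairings of a GATA-1 with an NLI array averaged 0.44, with 0.46 and 0.43 within the extraction days. Arrays of these 2 proteins thus resembled each other about as much as their replicates did. Pairings with RNA polymerase II arrays gave 0.24 to 0.33 for GATA-1 and 0.28 to 0.46 for NLI. A correlation near 0.44 before loess was therefore not particular to GATA-1 with NLI. After loess the replicate values were 0.70, 0.22 and 0.19, and GATA-1 with NLI averaged 0.20. With RNA polymerase II, GATA-1 then averaged 0.068 and NLI 0.075. Replicates shared 832 of their top 1000 windows for RNA polymerase II, 414 for GATA-1 and 352 for NLI.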

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

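Added after seeing the data were the restricted test of GATA-1 against NLI, normexp fitted on the random control probes, and the correlations after loess and normexp. Of 115 values named for single windows, 98 kept their direction and their side of the threshold in every alternative run for them (all on 500 bp windows, and not normexp on control probes); 14, all between 5.15 and 5.35 Mb of chromosome 11, lost their call in at least 1, and 3 differences of GATA-1 from NLI, named because they passed the restricted test, also passed over all windows without GATA-1 replicate 1. None reversed. Counts of enriched windows, overlaps and totals of differences stayed within 1.5 times under 1000 bp windows, Tukey centring, the deposited log2 ratios, removal of the dimmest probes, and fits of 4 arrays. A 1000 bp window covers more sequence than a 500 bp window, so that comparison is between unlike units and does not show stability to window size. Of the counts of enriched windows, overlaps and differences, quantile normalization moved the differences from RNA polymerase II (2618 for GATA-1, 1898 for NLI). With the replicate block the counts were 878 (GATA-1), 925 (NLI), 7740 (RNA polymerase II) and 442 (GATA-1 with NLI), none of these counts moved by over 1.5 times, and the named call it ended was GATA-1 at 5258501 of chromosome 11 (adjusted p = 0.0647). Depleted windows were less stable. From 60 for GATA-1 and 441 for NLI they went to 131 and 1693 with 1000 bp windows, 28 and 76 with 250 bp windows, 117 and 111 after quantile normalization, 23 and 34 without the dimmest probes, 31 and 154 with the replicate block, 15 and 8 after normexp, and 11 and 0 after loess. For RNA polymerase II, from 880, they went to 394 with 250 bp windows, 441 after normexp and 426 without the dimmest probes. With a minimum log2 ratio of 1 they were 2, 1 and 2. The causes were not tested.

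Other choices moved the counts further, and the causes were not tested unless given. Loess left 274 GATA-1, 126 NLI and 4927 RNA polymerase II windows, with overlaps of 89 (GATA-1 with NLI), 69 (GATA-1 with RNA polymerase II) and 34 (NLI with RNA polymerase II). Normexp left 331, 284 and 4639 windows, 2725 and 2480 differences of GATA-1 and NLI from RNA polymerase II, and overlaps of 174, 92 and 78. Windows of 250 bp, which hold fewer probes and cover less sequence each, gave 571 and 551 windows for GATA-1 and NLI, 2787 and 2439 differences, and overlaps of 261, 203 and 208. A minimum log2 ratio of 1, which by construction removes calls, left 370, 357 and 2903 windows, 2614 and 2308 differences, and overlaps of 217, 97 and 91. Normexp fitted on the random control probes left 0 GATA-1 and 0 NLI windows (limma; 3099 and 7258 windows at an unadjusted p under 0.05, against 3909 expected) and 1450 RNA polymerase II windows. The restricted test of GATA-1 against NLI called 14 windows where the test over all windows called 0. Correlations between replicates fell after loess to 0.22 (GATA-1), 0.19 (NLI) and 0.70 (RNA polymerase II), with 0.20 for GATA-1 with NLI, and after normexp to 0.17, 0.14, 0.60 and 0.15.

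Leaving out each array in turn, with a lone array assumed to vary like the others, gave 309 to 906 GATA-1 windows (lowest without GATA-1 replicate 2), 207 to 1564 NLI windows (lowest without NLI replicate 2, 469 without replicate 1) and 3622 to 8255 RNA polymerase II windows (lowest without its replicate 1, 5337 without replicate 2). GATA-1 against NLI gave 0 to 8 windows (8 without GATA-1 replicate 2, 5 without replicate 1). Differences from RNA polymerase II numbered 1933 to 4449 for GATA-1 and 1540 to 4129 for NLI, both lowest without RNA polymerase II replicate 1; without NLI replicate 2 the latter was 2105. Overlaps were 148 to 476 for GATA-1 with NLI (148 without NLI replicate 2, 194 without GATA-1 replicate 2), 119 to 346 for GATA-1 with RNA polymerase II (119 without GATA-1 replicate 2, 178 without RNA polymerase II replicate 1) and 98 to 574 for NLI with RNA polymerase II (98 and 203 without NLI replicates 2 and 1, 184 and 234 without RNA polymerase II replicates 1 and 2). Depleted windows ranged over 9 to 55 for GATA-1 (9 without its replicate 2, 19 with either RNA polymerase II array left out), 12 to 743 for NLI (12 and 36 without its replicates 1 and 2) and 36 to 1107 for RNA polymerase II (36 and 252 without its replicates 1 and 2). Signal over background limits all counts: input probes were 1.38 times the random probes on NLI replicate 1 and at most 2.02 times elsewhere. Alternatives planned for promoters and gene lists were not run, because genes were not placed on hg18.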

Other observations

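In this part, the profile of RNA polymerase II around shared sites, the spacing of those sites, and the correlation of GATA-1 with NLI arrays after loess were chosen after the results they bear on were seen. At the 458 windows enriched for both GATA-1 and NLI, RNA polymerase II averaged a log2 ratio of 0.69, with 0.76 on replicate 1 and 0.62 on replicate 2. The ratio was 0.27 at 10000 bp to the lower side (272 windows) and 0.19 at 10000 bp to the upper side (268 windows). These are fewer windows than the 458 at the sites, so the values do not compare the same set of sites. Circular shifts of the sites gave a mean of 0.06 and at most 0.18 (1000 shifts, permutation test, one-sided, p = 0.001, the smallest possible), and after loess the ratio at the sites was 0.45 against at most 0.13. The shifts did not match intensity, and 94.9% of GATA-1 and 99.0% of NLI windows lay above the median intensity. Before loess, the ratios at 10000 bp on both sides also exceeded the shifted maximum. The shifts therefore cannot separate RNA polymerase II at the sites from bright windows or from surroundings rich in RNA polymerase II. Of the 458 sites 211 were called for RNA polymerase II. Shared windows also lay closer to each other than windows drawn uniformly at random. Of 456 gaps between successive shared windows on a chromosome, 28.5% were longer than a window and up to 20 kb, against a mean of 12.6% and at most 16.9% in 200 random draws of as many windows. The draws did not match intensity or the uneven density of calls along the chromosomes. A gap could also be an uncalled window inside a single region. Whether separate sites cluster beyond this was not tested.

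GATA-1 and NLI arrays correlated with each other (0.44) about as strongly as replicates of either protein. Before loess NLI replicate 1 also reached 0.46 with RNA polymerase II replicate 2. After loess the pairings with RNA polymerase II averaged 0.068 for GATA-1 and 0.075 for NLI. An intensity trend common to the arrays would leave a correlation under 0.05 after loess, and the value after loess was 0.20, which argues against this trend as the whole cause, although the correlation fell from 0.44. Sites bound by both proteins may account for what remains. With every window within 2000 bp of an enriched window left out, the correlation after loess was 0.051 over 70573 windows. This lay just above the bound of 0.05 that this explanation needed and under the 0.10 that would have argued against it. The test cannot decide the question. Over those windows GATA-1 replicates correlated at 0.044 and NLI replicates at 0.0094, so 0.10 between the proteins could hardly have been reached. Leaving out enriched windows also removes shared high ratios of any cause. The explanation stays open.

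Windows of GATA-1 and NLI were often called for RNA polymerase II as well, and bright windows could be read as enriched for every protein. Of the GATA-1 windows 94.9% and of the NLI windows 99.0% lay above the median intensity. Within 20 bins of mean intensity, 245 of the 329 windows shared by GATA-1 and RNA polymerase II were expected, 0.74 of the observed number, and 0.66 of it after loess. Transcribed sequence may itself be bright and the immunoprecipitated signal adds to the intensity, so a technical overlap and binding near transcribed sequence cannot be told apart here. The overlap of GATA-1 with NLI differed in this respect, with 48.2 of 458 expected in the same bins.

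RNA polymerase II was called in 81.4% of the windows of the first megabase of chromosome 11, with medians of 0.95 and 0.75 on its 2 arrays, and 97.5% of these windows lay above the median intensity. If brightness alone were the cause, the share after loess would be under 1.5 times that of the chromosome. It was 53.7%, which is 7.23 times the 7.43% of chromosome 11 after loess and argues against the intensity trend as the whole cause. Base composition was not tested, since no hg18 sequence was used, and no biological explanation was tested.

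A hypothesis of another kind is that the RNA polymerase II windows from 5225501 to 5249000 of chromosome 11 (24 of 28 windows enriched) may be the β-globin gene cluster. By the GRCh38 gene list, 19 of the 20 protein-coding genes nearest to the β-like globin genes are olfactory receptor genes, expected to be silent in these cells, so RNA polymerase II was predicted to be rare in the flanks from 20000 to 150000 bp away. It was enriched in 31.0% of flank windows (90 of 290). This is above the 11.6% of chromosome 11, the level set beforehand as arguing against the hypothesis, so the prediction of rare RNA polymerase II failed. The upper flank had 78 of 159 windows enriched. The lower flank had 12 of 131 (9.16%), which is under the 11.6% of the chromosome but above the 2.91% that the prediction allowed. The test rests on the neighbours being silent and on the flanks lying outside the cluster. Neither was checked, because no gene was placed on the array and the bounds came from the highest RNA polymerase II regions. The flanks therefore cannot decide whether these windows are the β-globin cluster, and the hypothesis stays open.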
